A study of Macaca mulatta with 47 samples.

How the data were processed

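The samples were peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes separated from blood) of 16 rhesus macaques infected with simian immunodeficiency virus (SIV). Per the labels, 8 animals received interleukin-21 (IL-21) and 8 were controls, and each animal was sampled before antiretroviral therapy (pre-ART) and at 2 times named T1 and T2. The series' design text places the later samples during ART. The labels give days 58 to 59 for pre-ART, 105 to 107 for T1 and 240 to 242 for T2. They also give 4 groups, Gr1 to Gr4, called processing groups here, each with 2 IL-21 and 2 control animals. The dose and days of IL-21, the event from which days are counted and the genome build and annotation are not given in the sources used here. There were 47 libraries, with 8 in each group except IL-21 T2 (n = 7), where animal ROc10 had no library analysed here.

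Per the labels' protocols, total RNA was extracted with the RNeasy Micro kit, cDNA was made with the SMARTer HV kit and libraries with Nextera XT, and single reads of 100 bases were sequenced on an Illumina HiSeq. The submitters' processing notes name STAR 2.3.0e, Cufflinks 2.1.1 and Cuffdiff 2.1.1 without saying which made the values. The deposited table holds FPKM (fragments mapped to a gene, scaled by transcript length and library size) for 15845 genes and 47 columns, per the file headers, and every column matched 1 sample's label. Of its genes, 106 carry joint symbols and 4 have only an assembler's number. Symbols of 14114 genes matched those of a RefSeq annotation of the rhesus macaque, which was used for names alone, and 9058 of the tested genes matched. Upper quartiles were nearly equal between columns (19.55 to 21.41 FPKM), while column sums were 570376 to 846486 FPKM.

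The table gives no read counts, so absolute depth is unknown. Low values were searched for steps of 1 read over 2618 genes with 10 to 45 zeros, at a tolerance of 0.0005 on the log2 scale. Between pairs of 41 libraries 24.4% to 43.4% of the values above 0 in both shared a step. Relative depth of these libraries was 0.68 to 1.31 of the typical library, a 1.93-fold range. Median relative depth at pre-ART, T1 and T2 was 0.992, 0.973 and 1.06 in IL-21 animals and 0.989, 1.08 and 1.13 in controls. The 6 libraries of RLm12 (IL-21) and RBt12 (control) shared no such step (at most 3.63% of values), so their low values were made in some other way, and each comparison was run again without both animals.

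An exact 0 was not always absence: 776 genes were listed at 0 in every library, B2M among them. In 3 genes a whole group was listed at 0 while another had a median above 100 FPKM. CD74 was listed at 0 in every library except control pre-ART (5061 to 8089 FPKM), EEF1A1 in all T1 libraries and HBB in all T2 libraries. These 3 genes were taken as failed estimates and left out of every test, a departure from the plan, which had no such filter, and tests with them kept were run as an added alternative. CD3E, which the plan named, had no row of its own. HBA2 was used for haemoglobin.

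Genes with a mean of at least 1 FPKM over all libraries were tested (10035), on log2(FPKM + 1), with limma 3.58.1 in R 4.3.3, empirical Bayes with a trend and Benjamini-Hochberg adjustment. A call was an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of genes at low FPKM. Changes within animals were fitted on all libraries with the animal as a fixed block and time nested in arm: pre-ART to T1 and to T2 in each arm, the mean of both arms, T1 to T2, and the difference between arms in each change. ROc10 had no T2 library, but its pre-ART and T1 libraries entered this fit and so weighed on the IL-21 estimates that involve T2. Counts of animals and score changes that involve T2 cover only animals with both libraries. IL-21 and control animals at 1 time were compared with the libraries of that time alone. Values of near-identical copies (ribosomal proteins, CCL3L3, alpha globins, antigen-presentation genes) are uncertain, since reads could have been split between copies, and use of strand is not given.

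The pairing came from the animal names in the labels and was checked on the values. Deviations from group means correlated within animals with a median r across genes of 0.452 (pre-ART and T1), 0.498 (pre-ART and T2) and 0.426 (T1 and T2), against −0.0767, −0.052 and −0.0725 between animals of an arm. The lowest within-animal r was 0.253, and the animal's own library was the best match in 14 of 16, 15 of 15 and 13 of 15 animals.

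The 22 gene lists were interferon-stimulated, interferon-gamma response and antigen processing, cell cycle, inflammatory mediator, immediate early and stress, cytotoxic lymphocyte and natural killer (NK), T cell, T cell activation and exhaustion, B cell, plasma cell, monocyte, neutrophil, platelet, erythroid, plasmacytoid dendritic cell, IL-21 and STAT3 response, Th17, T follicular helper, regulatory T cell, complement and coagulation, oxidative phosphorylation and cytosolic ribosomal protein genes. Each was tested with camera (preset correlation of 0.01), with camera at an estimated correlation, and with fry, all adjusted over the 22 lists of a comparison. A list score was the mean log2(FPKM + 1) of its tested members. Score changes were tested by 2-sided permutation of signs over animals, enumerated in full, and score differences between arms by 2-sided exact permutation of arms, with Benjamini-Hochberg adjustment over 22 lists and 95% intervals from 10000 bootstrap resamples for differences between arms.

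Named genes followed a rule: per comparison, the 10 largest rises and 10 largest falls among calls whose direction was shared by at least 75% of the animals, up to 4 members of smallest p per list, and a fixed set (IL21R, SOCS3, BCL3, PRDM1, GZMB, PRF1, IFI44L, MX1, ISG15, MKI67, CD14, MS4A1, PPBP). Comparisons with fewer than 5 calls gave their calls and the 5 genes of smallest p. The text prints only a part of the genes so chosen. The lists, tests, design, this rule and the alternatives were chosen before the data were examined, except where a later choice is stated. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios size factors, quantile normalization, robust empirical Bayes, array weights, no animal block, a random animal block, the processing group as a covariate between arms, and leaving out each animal in turn.

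All tests were 2-sided. The fit was tested on simulated data in which 200 of 10035 genes were changed. A log2 change of 0.5 was recovered in 83% of changed genes for the change to T1 in controls, 94.5% for the mean of both arms at T1, 84.5% for the change to T2 in IL-21 animals, 56.5% for the difference between arms in the change to T1 and 70% for IL-21 against control animals at T1. For a change of 0.25 the shares were 21.5%, 63.5%, 18%, 4.5% and 0%. False calls numbered 0 to 15 per run. The simulated noise was drawn independently for each gene, so these figures do not cover correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.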

Results

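RNA of PBMC was sequenced from 16 SIV-infected rhesus macaques, 8 treated with IL-21 and 8 controls, before ART and at 2 times during ART. IL-21 is a cytokine made by helper T cells that signals through STAT3 and acts on B cells, NK cells and T cells. Each group had 8 libraries except IL-21 T2 (n = 7). The values were FPKM, with column sums of 570376 to 846486 (median 656211) and 12534 to 13171 genes above 0 per library. Haemoglobin HBA2, a red cell transcript, took 0.0268% to 8.11% of a library's sum. The first 2 principal components held 19.6% and 17.2% of the variance. Relative depth differed at most 1.93-fold between the 41 libraries in which it could be read. Each time had its own days, so a change over time and a difference between days cannot be told apart. Every processing group held animals of both arms.

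From pre-ART to T1, over both arms, the question was how blood cells of the same animals differed at the earlier time on ART. Interferon-stimulated genes fell. IFI27, a strongly interferon-induced gene, was 8.98-fold lower at T1 (log2 change −3.17, SE 0.349, limma adjusted p = 4.41e-07) and lower in 16 of 16 animals. ISG15, an antiviral ubiquitin-like protein, was 5.57-fold lower (−2.48, SE 0.276) and also lower in all 16. Its mean was 349 ± 309 FPKM before ART and 32.4 ± 13.6 at T1 in controls, and 334 ± 392 and 63.5 ± 68.6 in IL-21 animals (SD, n = 8 each). HERC5 (−1.89), the ligase that attaches ISG15, RSAD2 (−1.65) and CMPK2 (−1.54), both antiviral enzymes, and SIGLEC1 (−1.73), a sialic acid receptor of macrophages, fell as well. Of 48 tested interferon-stimulated genes, 45 were lower and 0 higher, and 48 were lower adjusted over the list alone (camera adjusted p = 2.33e-40, adjusted p = 0.203 with an estimated correlation). The list score changed by −1.01 ± 0.713 (SD, n = 16, permutation adjusted p = 0.00537), falling in 13 animals and rising in 3. Within processing groups it changed by −0.72, −1.09, −1.13 and −1.11.

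Genes of cytotoxic and dividing cells were lower at T1. The granule proteins PRF1 (−0.70, SE 0.134) and GZMB (−0.66, SE 0.143), which kill target cells, fell in 14 of 16 animals each, and NKG7 fell by 0.56. Of 27 cytotoxic and NK genes 16 were lower and 1 higher (19 and 1 adjusted over the list alone, camera adjusted p = 8.31e-08, adjusted p = 0.392 with an estimated correlation). PCNA, the DNA polymerase clamp, fell by 0.46 in 15 of 16 animals, with the replication helicase genes MCM5, MCM2 and MCM4. Of 45 cell cycle genes 28 were lower and 0 higher (35 lower adjusted over the list alone, camera adjusted p = 2.19e-13, adjusted p = 0.392 with an estimated correlation). MKI67, a marker of dividing cells, fell by 0.37. The checkpoint receptor LAG3 (−0.54) and the activation marker CD38 (−0.40) fell in 15 of 16 animals each. In the list of T cell activation and exhaustion genes 9 of 19 were lower and 2 higher, and the camera adjusted p was 0.0504. Its score changed by −0.134 ± 0.121 and fell in 14 of 16 animals (permutation adjusted p = 0.00537). GBP2 (−0.93) and GBP1 (−1.09), guanylate-binding proteins induced by interferon-gamma, were among 10 lower and 1 higher of the 23 interferon-gamma genes (12 and 1 adjusted over the list alone, camera adjusted p = 4.69e-05, adjusted p = 0.392 with an estimated correlation).

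The rises from pre-ART to T1 were smaller. CD14, the lipopolysaccharide co-receptor of monocytes, rose 1.57-fold (log2 0.65, SE 0.121, 14 of 16 animals) and CD36, a scavenger receptor, 1.91-fold (0.93, SE 0.174). Of 32 monocyte genes 14 were higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 2.43e-05, adjusted p = 0.57 with an estimated correlation). FCER1A, the alpha chain of the IgE receptor of basophils and dendritic cells, rose 1.96-fold, CD177, a neutrophil surface protein, 2.07-fold, and PDK4, which restrains glucose oxidation, 2.65-fold. IL7R, the interleukin-7 receptor of resting T cells, rose 1.55-fold in 16 of 16 animals and CD4 1.22-fold in 15. Among 72 cytosolic ribosomal protein genes 54 were higher and 0 lower (67 adjusted over the list alone, median log2 0.20, camera adjusted p = 1.63e-18, adjusted p = 0.392 with an estimated correlation). B cell genes were higher in 6 of 25 (6 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.665 with an estimated correlation), with CR2, a complement receptor of B cells, up 1.42-fold in 16 of 16 animals. Platelet genes were higher in 3 and lower in 1 of 24 (3 and 1 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.665 with an estimated correlation). Oxidative phosphorylation genes were higher in 7 of 48 (1 adjusted over the list alone, camera adjusted p = 7e-04, adjusted p = 0.665 with an estimated correlation). Over all genes 1299 of 10035 were called higher, so the platelet and oxidative phosphorylation counts lie near that share. IL-21 and STAT3 response genes were lower in 8 and higher in 3 of 27 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.392 with an estimated correlation).

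Other lists did not pass at T1. Th17 genes had 4 higher and 1 lower of 9 (camera adjusted p = 0.122), T follicular helper genes 3 and 3 of 12 (0.945), regulatory T cell genes 2 and 4 of 14 (0.893), plasmacytoid dendritic cell genes 1 and 3 of 10 (0.893), neutrophil genes 3 and 1 of 25 (0.893) and plasma cell genes 0 and 4 of 20 (0.176). T cell genes had 6 higher and 5 lower of 26 (camera adjusted p = 0.893), with a median of −0.04 beside a mean of 0.00. Complement and coagulation genes had 8 higher and 3 lower of 21 (camera adjusted p = 0.0798), inflammatory mediators 2 and 5 of 24 (0.473), immediate early and stress genes 6 and 9 of 33 (0.317) and erythroid genes 1 and 0 of 19 (0.5). Over all genes limma called 2594 of 10035 at T1, 1299 higher and 1295 lower, and 39 of the calls were over 2-fold. Without the animal block 723 were called.

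**Figure D1:**
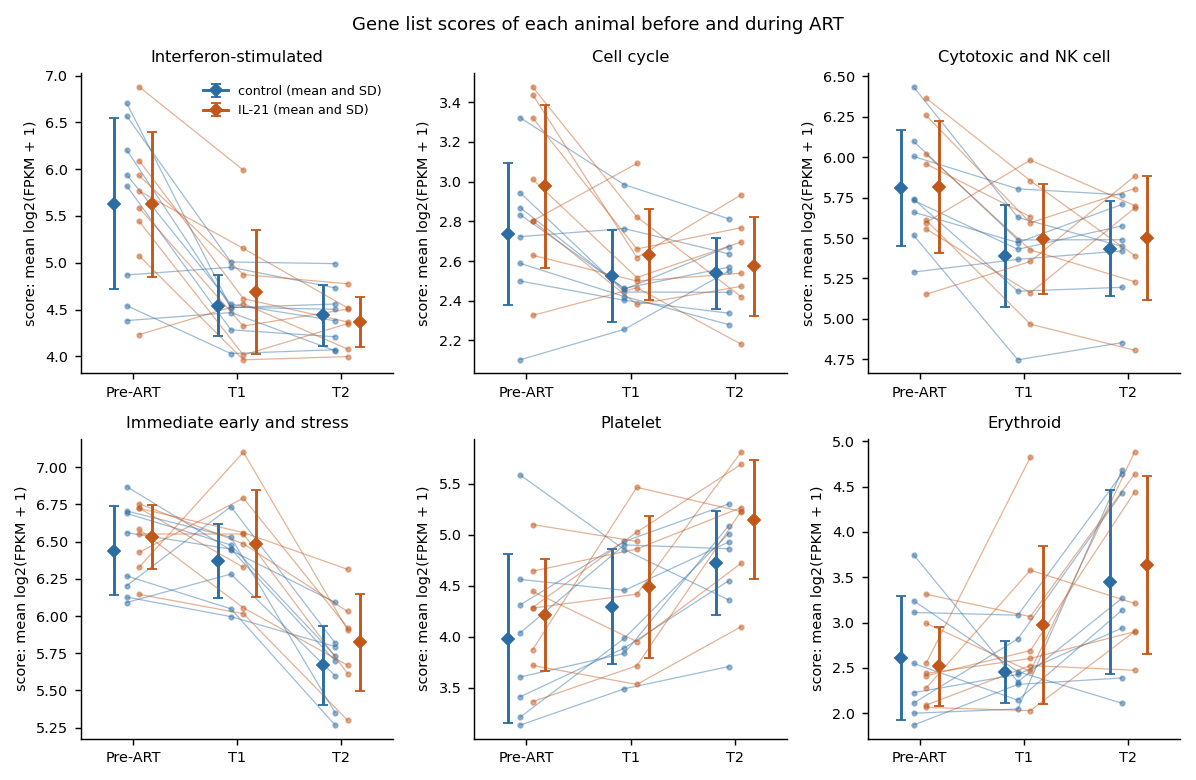
Score (mean log2(FPKM + 1) of tested members) of 6 gene lists at pre-ART, T1 and T2, with 1 line per animal and the mean and SD per arm as diamonds. The interferon-stimulated score was lower at T2 than before ART in 15 of 15 animals, and the platelet score was higher in 14 of 15.

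Taken arm by arm, the 2 largest falls at T1 were IFI27 and ISG15 in both. In controls IFI27 was 9.86-fold lower (log2 change −3.30, SE 0.494, limma adjusted p = 2.66e-04) and ISG15 6.53-fold lower (−2.71, SE 0.39), each in 8 of 8 animals. In IL-21 animals IFI27 was 8.18-fold lower (−3.03, SE 0.494, adjusted p = 6.94e-04) and ISG15 4.75-fold lower, also in 8 of 8. Of 48 interferon-stimulated genes 42 were lower in controls and 40 in IL-21 animals (47 and 45 adjusted over the list alone). The camera adjusted p was 2.95e-50 and 4.46e-32, with adjusted p = 0.0905 and 0.419 with an estimated correlation. Rises in controls included COCH, a secreted matrix protein, and VSIG4, a complement receptor of macrophages, each in 8 of 8 animals and by 0.97 and 0.84. In IL-21 animals CYP1B1, an enzyme of the aryl hydrocarbon response, was 3.59-fold lower in 8 of 8, and TPPP3, a tubulin-binding protein, was 1.96-fold higher in 8 of 8. CYP1B1 was also called lower in controls (log2 change −1.2, SE 0.187, limma adjusted p = 2.91e-04). Its mean at T1 was under 1 FPKM, 0.844 in IL-21 animals and 0.707 in controls, so these falls are understated. In all, 419 genes were called in controls (186 higher, 233 lower) and 1004 in IL-21 animals (486 higher, 518 lower). Both arms called 122 genes higher and 156 lower, where independent lists would share 9.01 and 12, and 0 genes were called in opposite directions. The arms share no animals, and their changes correlated across genes with r = 0.794, where genes are not independent replicates. Within each processing group both arms were sampled on the same days, so an effect of the day would also be shared by both arms. The smaller count in controls does not show a smaller change, since limma called 0 genes for the difference between arms in the change to T1 (191 at unadjusted p under 0.05). The control count was 188 without RGe12, 250 without RCb12, 143 without RJw12, 278 without RKg11, 24 without the animal block and 1010 with array weights. The IL-21 count was 486 without RJp11, 370 without RGv10 and 50 without the block.

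From pre-ART to T2 the same animals were compared at the later time on ART. IFI27 was 21.6-fold lower (log2 change −4.43, SE 0.358, limma adjusted p = 5.98e-11) and ISG15 8.7-fold lower (−3.12, SE 0.283), both in 15 of 15 animals. ISG15 fell to 21 ± 8.96 FPKM in controls (n = 8) and 22.1 ± 14.1 in IL-21 animals (n = 7). All 48 interferon-stimulated genes were lower (48 also adjusted over the list alone, camera adjusted p = 1.93e-19, adjusted p = 0.539 with an estimated correlation). Their score changed by −1.14 ± 0.62 (SD, n = 15), and its permutation p of 6.1e-05 is the smallest 15 animals can give (adjusted p = 2.68e-04). By processing group it changed by −0.925, −1.13, −1.1 and −1.47. Of 23 interferon-gamma genes 17 were lower and 2 higher (19 and 2 adjusted over the list alone, camera adjusted p = 1.47e-04, adjusted p = 0.539 with an estimated correlation), among them CD274, the checkpoint ligand PD-L1, which fell by 0.71 in 15 of 15 animals.

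Inflammatory and immediate early genes were lower at T2. PTGS2, the inducible cyclooxygenase, was 6.02-fold lower (−2.59, SE 0.292), IL1B, a cytokine of activated monocytes, 5.39-fold lower (−2.43, SE 0.307) and TNFAIP3, a brake on NF-kappa-B, 4-fold lower in 15 of 15 animals. KLF6 (−1.23), GADD45B (−1.27) and ATF3 (−1.52), transcription and stress regulators induced within hours of stimulation, fell in 15 of 15 each. Among 33 immediate early and stress genes 26 were lower and 1 higher (28 and 1 adjusted over the list alone, camera adjusted p = 1.06e-09, adjusted p = 0.495 with an estimated correlation), and their score fell in 15 of 15 animals, by 0.728 on average. Among 24 inflammatory mediators 11 were lower and 2 higher (12 and 3 adjusted over the list alone, camera adjusted p = 0.00326, adjusted p = 0.539 with an estimated correlation). IL-21 and STAT3 response genes were lower in 15 and higher in 3 of 27 (15 and 3 adjusted over the list alone, camera adjusted p = 0.00622, adjusted p = 0.539 with an estimated correlation). PRDM1, which drives plasma cell and effector T cell differentiation, fell by 0.98 in 15 of 15 animals, and SOCS3, a feedback inhibitor of STAT3, by 0.87 in 14 of 15.

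Red cell and platelet transcripts were higher at T2. ALAS2, the first enzyme of haem synthesis in erythroid cells, rose 6.97-fold (log2 2.80, SE 0.613, limma adjusted p = 3.09e-04) and HBA2 6.58-fold, each in 13 of 15 animals. TUBB1, the platelet tubulin, rose 2.99-fold (1.58, SE 0.207), GP1BB, part of the von Willebrand factor receptor, 2.63-fold and ITGB3, the platelet fibrinogen receptor chain, 2.58-fold, each in 14 of 15. Of 19 erythroid genes 17 were higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 1.67e-04, adjusted p = 0.547 with an estimated correlation). Of 24 platelet genes 22 were higher and 1 lower (22 and 1 adjusted over the list alone, camera adjusted p = 4.08e-08, adjusted p = 0.539 with an estimated correlation). The lower one was THBS1, thrombospondin, which monocytes also make (−2.06). The platelet score changed by 0.591, 1.14 and 1.67 in Gr1 to Gr3 and by −0.0786 in Gr4, and the erythroid score by 1.5, 0.99, 1.06 and 0.139.

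Single T cell genes were higher at T2, while cytotoxic and cell cycle genes were lower. IL7R rose 2.14-fold (log2 1.10, SE 0.0966), CD4 1.47-fold, CD40LG, the helper T cell ligand of CD40, 1.77-fold and TCF7, a factor of naive and memory T cells, 1.48-fold, each in 15 of 15 animals. As a list T cell genes did not pass, with 10 higher and 5 lower of 26 (camera adjusted p = 0.155). GZMA, a granule protease, was 2.01-fold lower and IFNG, the gene of interferon-gamma, 1.97-fold lower, while NCAM1, which encodes CD56, rose 1.71-fold in 15 of 15. Of 27 cytotoxic and NK genes 16 were lower and 2 higher (16 and 2 adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.666 with an estimated correlation). Of 45 cell cycle genes 33 were lower and 1 higher (33 and 1 adjusted over the list alone, camera adjusted p = 3.03e-06, adjusted p = 0.626 with an estimated correlation). FOXP3, the factor that defines regulatory T cells, rose 1.36-fold in 15 of 15, while IL10 fell by 1.13. The regulatory list had 6 higher and 5 lower of 14 (camera adjusted p = 0.948), with a test direction above 0 and a median of −0.05. Oxidative phosphorylation genes were lower in 22 and higher in 3 of 48 (22 and 3 adjusted over the list alone, camera adjusted p = 0.00622, adjusted p = 0.824 with an estimated correlation), a call lost under quantile normalization (0.553). Monocyte, B cell and ribosomal protein genes did not pass (12 higher and 2 lower of 32, 4 and 6 of 25, and 0 and 2 of 72), and the ribosomal median turned from −0.03 to 0.03 under quantile normalization. In all limma called 5290 genes at T2, 2730 higher and 2560 lower, with 154 over 2-fold.

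**Figure D2:**
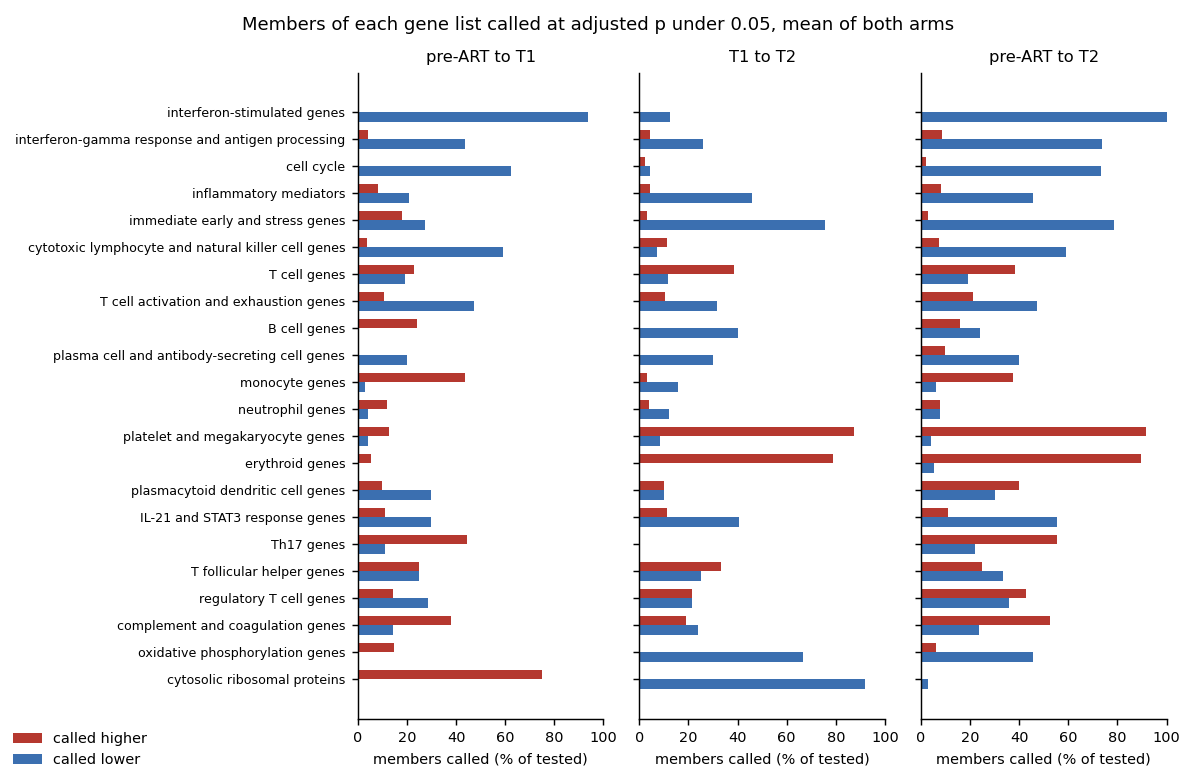
Percent of the tested members of 22 gene lists called higher or lower, mean of both arms, for pre-ART to T1, T1 to T2 and pre-ART to T2. Interferon-stimulated genes were lower in 45 and 48 of 48 from pre-ART to T1 and T2 and in 6 of 48 from T1 to T2.

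Taking the arms apart at T2, controls had 3641 calls (1731 higher, 1910 lower) and IL-21 animals 3663 (1870 higher, 1793 lower), against 1970 and 1911 without the animal block. Both arms called 1170 genes higher and 1409 lower, where independent lists would share 323 and 341, with 0 in opposite directions and r = 0.886 across genes. As at T1, the arms shared their days. In controls 44 of 48 interferon-stimulated genes were lower, with IFI27 22.6-fold lower (SE 0.494 on log2, limma adjusted p = 8.62e-08). In IL-21 animals 43 of 48 were lower, with IFI27 20.7-fold lower (SE 0.519, adjusted p = 5.99e-07). NFE2, a factor of platelet formation, rose 2.37-fold in controls in 8 of 8 animals. HBM and AHSP, an alpha-type globin and its chaperone gene, rose 5.21-fold and 5.11-fold in IL-21 animals, in 7 of 7 with a T2 library. The fit behind these 2 folds also held ROc10, which had no T2 library. Its erythroid score was 2.549 before ART and 4.826 at T1. Platelet genes were higher in 20 of 24 in controls and 22 of 24 in IL-21 animals, and erythroid genes in 8 and 16 of 19, where the difference between arms in the change called 0 genes (421 at unadjusted p under 0.05, limma). Immediate early genes were lower in 24 and 19 of 33.

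From T1 to T2, both on ART, immediate early and inflammatory genes fell and platelet and erythroid genes rose. PTGS2 was 6.34-fold lower (log2 change −2.66, SE 0.292, limma adjusted p = 7.43e-08), G0S2, an inhibitor of fat breakdown, 4.55-fold lower, IL1B 3.89-fold lower and OSM, an inflammatory cytokine, 3-fold lower, each in 15 of 15 animals. DUSP1, a phosphatase that ends MAP kinase signals, fell by 1.23 and EGR2 by 1.44. Among immediate early and stress genes 25 of 33 were lower and 1 higher (26 and 1 adjusted over the list alone, camera adjusted p = 5.91e-14, adjusted p = 0.152 with an estimated correlation). Their score changed by −0.76, −0.829, −0.521 and −0.658 in the 4 processing groups and fell in 15 of 15 animals. Among inflammatory mediators 11 of 24 were lower and 1 higher (13 and 1 adjusted over the list alone, camera adjusted p = 9.07e-04, adjusted p = 0.605 with an estimated correlation). Ribosomal protein genes were lower in 66 of 72 (69 adjusted over the list alone, camera adjusted p = 3.99e-17) and oxidative phosphorylation genes in 32 of 48 (34 adjusted over the list alone, camera adjusted p = 6.25e-10), both with adjusted p = 0.605 with an estimated correlation. The ribosomal call was lost under quantile normalization (camera adjusted p = 0.107). HBA2 rose 4.68-fold, SLC4A1, the red cell anion exchanger, 2.23-fold and TUBB1 2.13-fold. Platelet genes were higher in 21 and lower in 2 of 24 (camera adjusted p = 4.18e-07) and erythroid genes higher in 15 of 19 (1.21e-05; 22 and 2, and 16, adjusted over the list alone), both with adjusted p = 0.605 with an estimated correlation. B cell genes were lower in 10 of 25 (10 adjusted over the list alone, camera adjusted p = 0.00672, adjusted p = 0.932 with an estimated correlation) and T cell genes higher in 10 and lower in 3 of 26 (10 and 3 adjusted over the list alone, camera adjusted p = 0.00911, adjusted p = 0.886 with an estimated correlation, and camera adjusted p = 0.115 without RLm12 and RBt12). Interferon-stimulated genes were lower in 6 of 48 (camera adjusted p = 0.461), and ISG15 had −0.64 (SE 0.283, adjusted p = 0.071). In all 3868 genes were called, 1883 higher and 1985 lower, against 2294 without the animal block. T1 was compared with pre-ART and with T2 through the same T1 libraries, so the falls of one change and the rises of the other are not independent.

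IL-21 and control animals were then compared within each time, the question being whether IL-21 altered the blood transcriptome. At T1 the genes with the smallest p were GADD45A, a stress-induced growth arrest gene, at log2 0.82 (SE 0.214, IL-21 minus control), ZC2HC1A (−0.41), FSD1L (−0.49), PRMT10 (0.50) and CLC, the eosinophil and basophil galectin, at 1.99 (SE 0.581). None passed (limma adjusted p = 1), and limma called 0 genes, with 118 at unadjusted p under 0.05. Before ART limma called 0 (353 at unadjusted p under 0.05) and at T2 0 (683), where HIF1A, the oxygen-sensing transcription factor, had log2 0.59 (SE 0.119, adjusted p = 0.698). Without the filter 1 gene was called at T1, and with the 3 failed estimates kept 1 was called before ART, which was CD74. IL21R, the receptor of IL-21, had 0.15 (SE 0.117) at T1.

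As a list, IL-21 and STAT3 response genes were higher in IL-21 animals at T1. Their score was 4.744 ± 0.0978 in IL-21 and 4.549 ± 0.138 in control animals (SD, n = 8 each), a difference of 0.195 (95% bootstrap interval 0.0784 to 0.298, exact permutation p = 0.00777, adjusted p = 0.171 over 22 lists). Among 27 members 23 lay above 0, the median was 0.15, and 0 were called (0 adjusted over the list alone). The smallest p were of ID2, an inhibitor of helix-loop-helix factors (0.43, SE 0.129), SOCS1 (0.73, SE 0.288) and CISH (0.54, SE 0.249), feedback inhibitors of cytokine receptors, and PIM2, a STAT-induced kinase (0.36, SE 0.148). Camera gave an adjusted p of 1.57e-07, and 0.00806 with an estimated correlation, the only list in any comparison to pass that way, while fry gave 0.0994. Within processing groups the differences were 0.0925, 0.199, 0.222 and 0.267. In alternatives chosen after the data were seen, the adjusted p with an estimated correlation was 0.0551 without ROc10, 0.0617 without members shared with the cytotoxic or regulatory lists and 0.00519 without those shared with the immediate early list. Over all alternatives in which it was computed it ranged from 3.19e-04 to 0.0617. The score also lay 0.141 higher in IL-21 animals before ART (exact permutation p = 0.121) and 0.158 higher at T2 (exact permutation p = 0.0145, adjusted p = 0.16), and within processing groups before ART it differed by 0.18, 0.156, 0.389 and −0.163. Before ART the members of smallest p were CD274 (log2 0.54, SE 0.13), IRF4 (0.22, SE 0.0873), PRDM1 (0.31, SE 0.145) and IL18R1 (0.21, SE 0.111). Each was higher in IL-21 animals then, and none was called. They were chosen by their p before ART and are not the members named at T1. The change to T1 differed between arms by 0.52 (SE 0.338) for CISH, 0.30 (SE 0.166) for PIM2 and 0.38 (SE 0.379) for SOCS1. For CD274 it differed by −0.28 (SE 0.187), and none of these was called. Of the 27 members 14 also belong to another list.

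**Figure D3:**
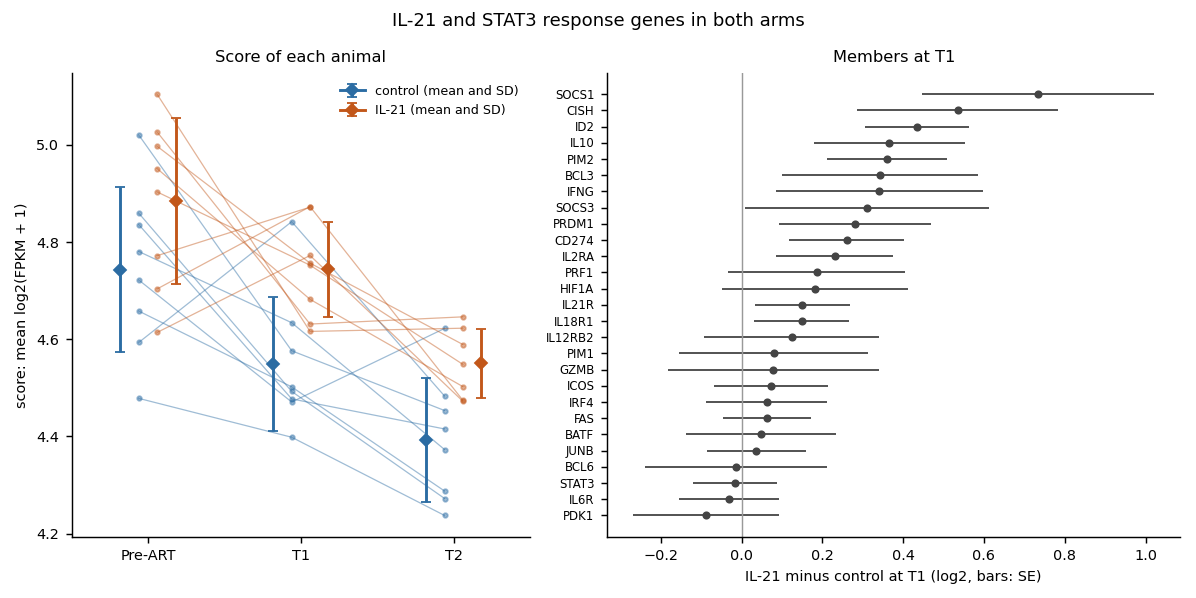
Left, score of the IL-21 and STAT3 response list (mean log2(FPKM + 1)) of each animal by arm and time; right, log2 difference of its 27 members at T1, IL-21 minus control, with SE. At T1, 23 of 27 members lay above 0, and the arms' mean scores were 4.744 and 4.549.

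With the preset correlation camera passed 12 of 22 lists between arms at T1, the IL-21 and STAT3 list among them, and 7 each before ART and at T2. With an estimated correlation every one of these calls except that of the IL-21 and STAT3 list at T1 was lost, with adjusted p of 0.0617 to 0.715 at T1, 0.591 to 0.882 before ART and 0.121 to 0.798 at T2. The largest score differences at T1 were of neutrophil and erythroid genes. The neutrophil score was 2.523 ± 1.45 in IL-21 and 1.855 ± 0.497 in control animals (SD, n = 8 each), a difference of 0.668 (95% bootstrap interval −0.145 to 1.75, exact permutation p = 0.241, adjusted p = 0.863). Camera gave 1.57e-07, with adjusted p = 0.596 with an estimated correlation, and without ROc10 the difference was 0.176 and the camera adjusted p 0.116. The erythroid score was 2.972 ± 0.877 against 2.454 ± 0.343 (SD, n = 8 each), a difference of 0.517 (95% bootstrap interval −0.0224 to 1.18, exact permutation p = 0.137, adjusted p = 0.863). Camera gave 2.07e-09, with adjusted p = 0.301 with an estimated correlation, and without ROc10 the difference was 0.253 and the camera adjusted p 6.07e-04. Within processing groups the neutrophil difference was 0.203, −0.326, 0.537 and 2.26 and the erythroid 0.15, 0.0413, 0.523 and 1.36. Interferon-stimulated, interferon-gamma, cell cycle, inflammatory, cytotoxic, plasma cell and platelet genes passed at T1 with medians of 0.0595 to 0.215, and monocyte genes with −0.123. Leaving out 1 animal ended each of these calls except that of plasma cell genes (camera adjusted p without that animal in parentheses). Interferon-stimulated genes lost the call without RKg11 (0.131), ROc10 (0.419, with the sign turned) and RHa10 (0.121). Interferon-gamma genes lost the call without ROe12 (0.142), RPu12 (0.118) and ROc10 (0.0528). Cell cycle genes lost the call without ROc10 (0.147). Inflammatory genes lost the call without ROe12 (0.179), RKg11 (0.131), RPu12 (0.416), ROc10 (0.32), RKd12 (0.0701), RPy8 (0.0701) and RHa10 (0.238). Cytotoxic genes lost the call without RBt12 (0.0594), RCb12 (0.12), RJw12 (0.938), RVt10 (0.252), RTb12 (0.0571), ROc10 (0.147) and RHa10 (0.463). Monocyte genes lost the call without RLm12 (0.282), RBt12 (0.328), RCb12 (0.146), RJw12 (0.601), RVt10 (0.138) and RTb12 (0.693). Platelet genes lost the call without RBt12 (0.104), RGe12 (0.375), RJp11 (0.679), RGv10 (0.163), RKg11 (0.0641), RPu12 (0.163), ROc10 (0.188) and RHa10 (0.0973). At T1 regulatory T cell genes, with FOXP3 at 0.39 (SE 0.137), had a score difference of 0.183 (exact permutation p = 0.0297, adjusted p = 0.327) and camera adjusted p = 1.34e-04, and adjusted p = 0.0617 with an estimated correlation. Within processing groups it was 0.235, 0.244, 0.306 and −0.0513. Before ART the difference was 0.129 (exact permutation p = 0.119), and the change to T1 differed by 0.0545 (exact permutation p = 0.393). At T2 Th17 genes, which mark interleukin-17-making helper T cells, lay higher in IL-21 animals in 9 of 9 members, with PTPN13, a phosphatase, at 0.52 (SE 0.132). Their score was 3.851 ± 0.135 against 3.629 ± 0.135 (SD, n = 7 and 8, exact permutation p = 0.00777, adjusted p = 0.16), and camera gave 0.00354, with adjusted p = 0.121 with an estimated correlation. By processing group the Th17 difference was 0.187, 0.179, 0.324 and 0.209. Fry passed for 0 of 22 lists between arms at each time.

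The changes to T1 and T2 were not called different between the arms for any gene. For the change to T1 limma called 0 genes (191 at unadjusted p under 0.05), with PRKCI, a polarity kinase, of smallest p (log2 −0.37, SE 0.102, adjusted p = 1). For the change to T2 it called 0 (421), with APP, the amyloid precursor gene, of smallest p (0.49, SE 0.129, adjusted p = 0.968). With the 3 failed estimates kept, 1 gene, CD74, was called in each. Camera with the preset correlation passed 6 and 10 of 22 lists, and 0 with an estimated correlation or fry. The IL-21 and STAT3 score changed by −0.1395 ± 0.255 in IL-21 and −0.1943 ± 0.219 in control animals to T1 (SD, n = 8 each), a difference of 0.0548 (95% bootstrap interval −0.172 to 0.269, exact permutation p = 0.644). To T2 the T follicular helper score changed by −0.1223 ± 0.117 in IL-21 animals (n = 7) and by 0.07461 ± 0.194 in controls (n = 8, exact permutation p = 0.0281, adjusted p = 0.307). The Th17 score changed by 0.1601 ± 0.114 and −0.001891 ± 0.0981 (exact permutation p = 0.0131, adjusted p = 0.288), and the monocyte score by 0.2475 ± 0.274 and −0.08679 ± 0.296 (exact permutation p = 0.0418, adjusted p = 0.307). By the permutation test of scores, none of the 22 lists passed adjustment for either change.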

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

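Of the tests below, those of monocytes, of sampling day and of dilution by platelet and red cell RNA, that of the arms' difference before treatment and the list tests leaving out 1 animal were chosen only after the result was seen.

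The fall of the interferon-stimulated score to T1 was weighed against changes in the samples. Fewer monocytes would lower the monocyte score, which changed by 0.266 (95% interval 0.0229 to 0.509, n = 16) and, without RLm12 and RBt12, by 0.164 (−0.0478 to 0.376, n = 14), both far from the −1.01 of the interferon-stimulated score, so they are argued against as the whole cause. A single processing group as carrier of the fall is argued against, since the mean change was −0.72 or lower in each of the 4 groups. Every animal fell in 2 of the 4 groups, 3 of 4 in Gr2 and 2 of 4 in Gr1. The stricter bound set beforehand, that every animal fall in each group, was thus not met. The day or library batch of T1 cannot be told apart from time, since all groups fell (least negative mean −0.72) and no group had its times on 1 day. Lower viral load on ART is a biological candidate explanation that no value here tested.

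For the fall of immediate early genes and the rise of platelet genes from T1 to T2, dilution of leukocyte RNA would lower all leukocyte genes alike, but immediate early genes fell further than the mean of the T cell, B cell and monocyte scores (−0.588, 95% interval −0.765 to −0.41, 15 of 15 animals; −0.527, −0.703 to −0.351, without RLm12 and RBt12), which argues against it as the cause of their fall. The T cell score alone (0.134, 95% interval 0.0166 to 0.251; 0.0905, −0.0249 to 0.206, without both animals) decides nothing, since the columns have nearly equal upper quartiles, and B cell and ribosomal protein genes were lower. A handling difference between sampling days could lie behind both changes. The relation set beforehand for it was a larger platelet rise with a larger immediate early fall, thus a Pearson r below 0. Over 15 animals the changes of the scores had Pearson r = 0.315 (permutation p = 0.252) and Spearman rho = 0.364 (permutation p = 0.182, 1 relation tested). Without the 2 animals farthest from the median r was 0.657, and within processing groups 0.101. Every value lay above 0, so the predicted relation was not seen. The opposite relation did not pass its permutation test either, which leaves a handling difference open, with longer ART untested beside it.

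IL-21 and STAT3 response genes lay higher in IL-21 animals at T1. A single processing group is argued against, since the smallest difference of the 4 was 0.0925, and so are the 2 animals whose low values were made in another way, since the camera adjusted p without both was 1.13e-09. A difference between the arms from before treatment stays open, since the arms' changes to T1 differed by 0.0548 (exact permutation p = 0.644) and the pre-ART scores by 0.141. An effect of IL-21 may remain beside it, and these data cannot tell the explanations apart.

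Exchanging time points within animals tested the counts of genes against chance. For the change to T1 in controls, 2 of 100 splits called as many as the real 419, and 1 exchanged split called more (427), so chance is less likely there but not ruled out. For the other 6 changes 1 split, the real one, called as many, the smallest share that 64 or 100 splits can give. Chance is therefore unlikely there, but so few splits cannot exclude it. For T2 in controls the real count was 3641, against at most 2307 in an exchanged split (100 splits). In IL-21 animals the counts were 1004 against 850 for T1 (100) and 3663 against 2294 for T2 (64). In both arms they were 2594 against 539 for T1 (100), 5290 against 1829 for T2 (100) and 3868 against 1158 for T1 to T2 (100). In the 5 comparisons of arms the real count was 0, so 100 of 100 splits called as many by construction and the splits say nothing about chance. Any gene was called in 5 of 100 splits for the difference in the change to T1 (highest 1312), 9 at T1 (674), 3 before ART (21), 2 for the change to T2 (9) and 8 at T2 (8), with a median of 0 in each. No structure of the samples behind the splits with many calls was tested.

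Single animals stood apart from their group in 14 of 222 groups of values, where chance gives about 1 in 20 groups, or 11.1. An animal stood apart when it had the highest or lowest value of its 7 or 8 animals and its gap to the nearest other, divided by the group's whole range, lay above Dixon's 95% critical value for that number of animals. The smallest such ratio among the 14 was 0.528. RJw12 (control) gave 5 and ROc10 (IL-21) 4. In list scores, RJw12 had the highest monocyte score at T2 (7.769, next 7.256), the highest neutrophil score at T1 (3.025, next 1.888) and the lowest Th17 score at T1 (3.363, next 3.688). ROc10 had the highest neutrophil score at T1 (5.97, next 2.607) and the lowest T follicular helper score before ART (3.754, next 4.18), and RKg11 the highest ribosomal score at T1 (11.41, next 11). In log2(FPKM + 1), SOCS3 was lowest in ROc10 before ART (5.664, next 6.204) and highest in RBt12 at T1 (7.568, next 6.275) and in RJw12 at T2 (7.194, next 5.357). PRF1 was highest in RGe12 before ART (8.032, next 7.218), CD14 in RJw12 at T2 (8.378, next 7.518), MS4A1 lowest in ROc10 at T1 (4.761, next 6.43) and PPBP lowest in RLm12 at T1 (7.406, next 9.05). RGv10 had the fewest genes above 0 FPKM at T1 among IL-21 animals (12530, next 12740).

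In 16 list tests, 6 for the change to T1 and 10 for the change to T2, on 11 different lists, the change differed between the arms by camera with the preset correlation, none with an estimated correlation (smallest adjusted p = 0.48) or fry. The medians of IL-21 minus control for the change to T1 were 0.172 for interferon-stimulated, −0.153 for cell cycle, 0.108 for B cell, 0.766 for neutrophil, 0.491 for erythroid and 0.111 for ribosomal protein genes. For the change to T2 they were −0.12 for interferon-gamma, −0.184 for cell cycle, −0.351 for B cell, 0.322 for monocyte, 0.631 for neutrophil, 0.3 for platelet, 0.313 for erythroid, −0.166 for T follicular helper and 0.137 for complement genes. Ribosomal protein genes had 0.0872, which turned to −0.0329 under quantile normalization. No score difference passed adjustment over 22 lists. These differences often rested on single animals, and 8 of the 16 lost the call or turned in sign when 1 animal was left out (median without that animal in parentheses). ROc10 had no T2 library, so leaving it out moved the change to T2 only through its pre-ART and T1 libraries in the fit. The call was lost or turned for the change to T1 for B cell genes without RBt12 (0.0239), RGv10 (0.0915), RCb12 (0.0438), RJw12 (0.136), RVt10 (0.078), RTb12 (0.0394), RKg11 (0.0819) and RPy8 (0.095). Interferon-stimulated genes lost it without ROe12 (−0.0331), RGe12 (−0.00448), RJw12 (0.0868), RPu12 (0.0769), ROc10 (0.179), RKd12 (0.131), RPy8 (0.0852) and RHa10 (0.144). Ribosomal protein genes lost it without RGv10 (0.0291). Erythroid genes lost it without ROc10 (0.253). With the call kept, the median to T1 moved by over 1.5 times for B cell genes without RLm12 (0.163), ROe12 (0.179), RGe12 (0.28), RPu12 (0.168), RKd12 (0.167) and RHa10 (0.218). Interferon-stimulated genes moved likewise without RBt12 (0.29), RCb12 (0.301) and RKg11 (0.26). Ribosomal protein genes moved likewise without RJp11 (0.0643), RCb12 (0.0634) and ROc10 (0.204). Cell cycle genes moved likewise without RGv10 (−0.094), RTb12 (−0.0823), RKg11 (−0.0943) and ROc10 (−0.231). Neutrophil genes moved likewise without ROc10 (0.444). The call was lost or turned for the change to T2 for erythroid genes without ROe12 (0.144), ROc10 (0.194), RKd12 (0.077), RPy8 (0.117) and RHa10 (0.171). Interferon-gamma genes lost it without RKg11 (−0.0615). Platelet genes lost it without RVt10 (0.187), RTb12 (0.157) and RKd12 (−0.00507). Complement genes lost it without RKd12 (0.105). With the call kept, the median to T2 moved by over 1.5 times for erythroid genes without RBt12 (0.608), RJp11 (0.509), RVt10 (0.471) and RPu12 (0.544). Ribosomal protein genes moved likewise without ROe12 (0.0578), ROc10 (0.132) and RHa10 (0.0573). B cell genes moved likewise without RGe12 (−0.135). Interferon-gamma genes moved likewise without RGv10 (−0.0757). Cell cycle genes moved likewise without RGv10 (−0.0754) and RKg11 (−0.0952). Neutrophil genes moved likewise without RJw12 (0.353). For the neutrophil score the difference in the change to T1 was 0.717 with all animals and 0.455 without ROc10, and for the erythroid score 0.608 and 0.347.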

How the results depend on the processing

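Keeping the 3 failed estimates, leaving out RLm12 and RBt12, leaving out 1 animal in list tests, and removing from the IL-21 and STAT3 list its members shared with the immediate early list or with the cytotoxic or regulatory lists were alternatives chosen after the data were seen. Counts of called genes stayed within 1.5 times under a pseudocount of 0.1, a filter at 5 FPKM, both scalings, robust empirical Bayes and a random block in the 7 changes. Without the animal block, fewer genes were called: 24 and 1970 in controls at T1 and T2, 50 and 1911 in IL-21 animals, 723 at T1 in both arms and 2294 from T1 to T2. Array weights gave 1010 in controls at T1. Leaving out 1 animal gave 143 to 616 in controls and 370 to 1375 in IL-21 animals at T1 and 0 between arms. The difference of the IL-21 and STAT3 score at T1 was 0.174 to 0.237 leaving out 1 animal. With the failed estimates kept 1 gene, CD74, was called in each difference of changes and before ART, and without the filter 1 at T1. With the processing group as a covariate, or all 47 libraries with a random animal block, 0 were called between arms at each time, as with the other settings not named here. Over all comparisons camera called 116 list tests, against 1 with an estimated correlation and 54 with fry, and 113 to 126 otherwise. A turn in sign was seen for cytosolic ribosomal proteins: difference between arms in the change to T2, under quantile normalization (camera adjusted p = 0.0182), and monocyte genes between arms at T1 without RLm12 and RBt12 (0.886). Leaving out 1 animal, 37 of the 116 list calls were lost or turned, though none of the calls in the mean of both arms was. Turns in sign by camera adjusted p were seen for interferon-stimulated genes: difference between arms in the change to T1 (4.24e-08 to 0.628), platelet and megakaryocyte genes: difference between arms in the change to T2 (4.64e-06 to 0.998) and interferon-stimulated genes: IL-21 against control animals at T1 (9.54e-09 to 0.419, the last without ROc10). Of 592 named-gene results none turned in sign, but 233 lost their call without the animal block, 39 without the filter, 32 with array weights, 31 with a random block and 24 under quantile normalization, and 439 of 9472 tests of them leaving out 1 animal did. The cause was not tested. Absolute depth is unknown, which limits genes near 0 FPKM.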

Other observations

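The test of the aryl hydrocarbon receptor below was written before its targets were looked at, while TIPARP was chosen after its values were seen and is outside the rule for named genes.

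TIPARP, an ADP-ribosyltransferase that the aryl hydrocarbon receptor induces and that restrains it, fell at each step. Its log2 change was −0.94 (SE 0.0742, limma adjusted p = 6.01e-10) from pre-ART to T1 and −1.61 (SE 0.0761, adjusted p = 3.16e-16) to T2. In IL-21 animals its mean was 59.8 ± 11.9 FPKM before ART (SD, n = 8), 26.7 ± 5.51 at T1 (n = 8) and 16 ± 1.96 at T2 (n = 7), and in controls 41 ± 9.26, 23.8 ± 3.91 and 14.2 ± 1.1 (n = 8 each). CYP1B1, an oxidase that the same receptor induces, had −1.52 to T1 and −2.06 to T2. Its mean in IL-21 animals was 5.68 FPKM before ART, 0.844 at T1 and 0.123 at T2, and in controls 3.37, 0.707 and 0.108. At values this low the log2(FPKM + 1) scale understates the fall.

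Lower activity of this receptor was tested as a hypothesis for both falls. Of 10 other targets listed, 2 passed the filter, NQO1 and NFE2L2, with a median log2 change to T2 of 0.203. Both were called higher (0.20, adjusted p = 0.0207, and 0.20, adjusted p = 0.0282, limma) and 0 lower. By the bound set beforehand (a median of 0 or above) the prediction of lower receptor activity was not met. The test cannot decide on receptor activity, since only 2 of 10 targets could be measured and TIPARP and CYP1B1, which the receptor also induces, fell.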
